A study of Mus musculus with 2 samples.

How the data were processed

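Spatial RNA profiles of 2 mouse hearts were deposited, 1 section from a male and 1 from a female, both with the genotype Ctla4+/-Pdcd1-/-. Sections were formalin-fixed and paraffin-embedded, and were profiled on the Visium HD platform with sequencing on an Illumina NovaSeq instrument, per the labels' protocols. On such sections the platform reads RNA through gene-specific probes, so that a gene is seen only where its probes bind. The deposited values are unique molecular identifier (UMI) counts per gene and per 2-µm square bin, made with Space Ranger 3.0.0, per the file headers. The submitters' processing notes name Space Ranger and the mm10 genome build. The probe positions within each gene are not given in the sources used here, and the section images were not used here. Gene symbols were taken from the deposited gene tables. No control heart without the genotype and no heart of the wild type is part of the data used here.

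Each array held 11222500 bins and all of them were marked as tissue, so that the mark separated no tissue from glass. Bins were summed to 16 µm, and a 16-µm bin was kept where it held at least 50 UMIs and the mean over its 3 × 3 neighbourhood was at least 500 UMIs. This density mask was chosen after the depth had been seen and before any test was run. The male section kept 77110 bins (19.7 mm²) with 138847738 UMIs and the female section 69847 bins (17.9 mm²) with 158639140 UMIs.

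All zones were set from a list of 18 leukocyte genes, the definers (Ptprc, Coro1a, Laptm5, Lcp1 and others). They were left out of the tests of focus and border against remote. Where zones were set from T cell genes as an alternative, those genes were left out instead. The leukocyte share is definer UMIs over all UMIs in a window of 3 × 3 bins (48 µm). A focus bin lay in the top 5% of its section by this share and in a connected patch of at least 10 such bins. Border bins lay outside the top 5% and within 50 µm of a focus. Remote bins lay more than 100 µm away from any bin of the top 5% and had a leukocyte share below their section's median. Anatomy was set over windows of 5 × 5 bins (80 µm) with at least 10 UMIs of both lists together. A bin was put in the atrial class where UMIs of the atrial list (Myl7, Sln, Myl4, Dkk3, Bmp10) exceeded those of the ventricular list (Myl2, Myl3, Irx4), and in the ventricular class in the reverse case. Within foci, 8-µm bins with at least 1 UMI of Cd8a or Cd8b1 and none of Cd4 were called CD8 bins, and those with Cd4 and neither of the others CD4 bins. Their neighbourhoods were bins at a distance of 1 or 2 bins without any UMI of these genes and near a bin of 1 kind only. Cd8a, Cd8b1 and Cd4 were left out of the tests of CD8 against CD4 bins and neighbourhoods. The definers stayed in these tests and can be among their counted calls. Bins hold RNA of several cells or parts of cells, so that zones and bin classes are regions and not cell types. Bins with more than 0.1% of UMIs from a list of airway, squamous epithelial and skeletal muscle markers are called extracardiac.

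UMIs were summed per heart and zone, which gave 4 sums from 2 hearts in each comparison. The sums were tested with edgeR 4.0.16 (quasi-likelihood test with robust fit, TMM scaling, filterByExpr) with the heart as a block and Benjamini-Hochberg adjustment at 0.05. Both zones of a pair come from the same heart per the labels, and the residual had 1 degree of freedom per gene. The spread of a gene was shared across genes, with a median of 2.97 prior degrees of freedom for focus against remote, 3.27 for border against remote and 48.9 for CD8 against CD4 bins. For the neighbourhoods the estimate was infinite, so that adjusted p there rests on a spread common to all genes. Values are fitted log2 fold changes ± SE with n = 2 hearts. The SE was derived from the test statistic with the shared spread. It is not the spread between the 2 hearts and can be small where they disagree. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, adjusted over the 39 lists. The preset correlation is an assumption. The estimated correlation and fry rest on 1 residual degree of freedom per gene, so a list that does not pass with them is not thereby refuted. Further tools were DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A single heart per sex allows no test of sex. Male and female values are therefore given as CPM, UMIs scaled to the section or zone total, with exact Poisson 95% intervals, and shares of bins and of UMIs with exact binomial 95% intervals, which cover counting error only. For shares of bins the intervals treat neighbouring bins as independent, although their windows overlap, and are too narrow. The median ratio of a list is placed among 10000 random lists matched on mean expression. A gene at 0 UMIs was bounded by 3 counts.

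Zones, lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except where stated. For each tested comparison the text names the 10 largest and the 10 smallest log2 fold changes among genes with adjusted p under 0.05, at least 20 CPM in the higher zone and the same direction in both hearts. If fewer passed, the choice is among all that pass. It also names 2 per list by smallest adjusted p, and always Pdcd1, Ctla4, Cd8a, Cd4, Ifng, Gzmb, Cxcl9, Cxcl10, Gja1, Nppa and Nppb. A few genes that the rule names are not reported here. For male against female it names the 8 largest ratios each way among genes with at least 500 UMIs in a section. List members called against the direction of most called members of their list (Hmox1, Atf3, Fkbp1b, Gbp6, Igtp, Irgm1, Psmb10, Cxcl12 and Notch3), and the Trbv segments, were named after their values had been seen. The number named per list was set at 2, within a range of 2 to 4, also after values had been seen. Genes with near-identical copies (hemoglobin, immunoglobulin and T cell receptor genes) are uncertain where probes can bind more than 1 copy.

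The test was tried on simulated counts with the depth of the real sums. Each heart kept 1 mean per gene for both zones, except in 200 changed genes. In focus against remote (14318 genes) it recovered 8.20% of genes changed 1.5-fold, 43.9% at 2-fold and 78.7% at 4-fold, and 75 of its 157 calls were false. In border against remote (14528 genes) the shares were 4.62%, 35.5% and 77.8%, with 40 false calls of 114. For CD8 against CD4 bins (10635 genes) they were 17.9%, 42.2% and 83.9%, with 6 of 97 false, and for the neighbourhoods (11700 genes) 13.8%, 38.3% and 53.0%, with 2 of 69 false. False calls thus exceeded the nominal 5% in the zone comparisons. At the unadjusted p that the real calls reached, 391 unchanged simulated genes passed beside 5995 real calls for the foci and 260 beside 4446 for the borders. For the bins 5 passed beside 59 and for the neighbourhoods 2 beside 77. Only 200 genes were changed and the simulated zones did not differ in composition or anatomy, so these counts give no error rate for the real calls.

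Alternatives covered the scaling (library sizes only, DESeq2), the low-count filter, the block, zones fitted together, other thresholds and bin sizes, zones set from T cell genes, anatomy classes, wider borders, remote bins matched on cardiomyocyte share, and leaving out each heart. Alternatives without the density mask, with a mask at 1000 UMIs, without extracardiac bins and with atrial-class bins only were chosen after seeing the data. Xist, Ly6c2, Ptcra, Mx1 and Ccnb1 were fixed in lists and are not among the 19059 genes measured. The single-cell and T cell receptor sequencing that the series describes was not analysed here.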

Results

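Hearts of Ctla4+/-Pdcd1-/- mice, a model of the myocarditis that checkpoint inhibitor drugs can cause, were profiled as 1 male and 1 female section. The male section held 145613600 UMIs and the female section 163200661. A kept 16-µm bin had a median of 1767 UMIs and 1017 genes in the male heart, and of 2208 UMIs and 1195 genes in the female heart. In the male heart 19019 of the measured genes were detected and in the female heart 19008. Mitochondrial genes took 10.1% of male and 8.86% of female UMIs.

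The deleted gene Pdcd1, which encodes the inhibitory receptor PD-1, had 0 UMIs in both hearts, which allows up to 0.0216 CPM in the male and 0.0189 CPM in the female heart. Ctla4, of which an allele is deleted, had 3709 UMIs (26.7 CPM) in the male and 4757 UMIs (29.99 CPM) in the female heart. Whether its probes lie inside the deleted part is not given in the sources used here, so its level does not check the label. The Y-linked genes Ddx3y (18894 UMIs), Kdm5d (5749), Uty (5654) and Eif2s3y (6898) were counted in the male heart only, with 0 UMIs in the female heart. Cd8a had 14312 UMIs in the male and 20596 in the female heart, and Cd4 had 2775 and 3881.

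Leukocyte foci filled 72 patches with 3414 bins in the male heart and 83 patches with 2860 bins in the female heart. The border held 6494 and 5916 bins and the remote zone 36293 and 33240. Zone sums ranged from 8067755 UMIs in the female foci to 68748728 in the female remote zone. The zones differed in anatomy. Of male bins, 34.5% of the focus and 56.5% of the remote zone were of the atrial class, against 65.0% and 7.67% of female bins. The male section also held tissue with airway, squamous epithelial and fast skeletal muscle transcripts. It lay in 10.7% of remote, 6.47% of border and 4.98% of focus bins, and in 0 bins of the female section. The airway secretory genes Scgb1a1 (222035 UMIs against 28) and Bpifa1 (218637 against 24) and the skeletal muscle genes Myh8 (10659 against 24) and Tnnc2 (9359 against 41) marked it. In 6043 extracardiac bins lay 98.3% of male Scgb1a1 and 97.1% of male Myh8 UMIs. Both genes belong to the list that set these bins. Of the squamous epithelial genes in that list, 71.8% of male Krt13 and 70.9% of male Krt4 UMIs lay there. The atrial list stood at 11692 CPM in the male and 135 CPM in the female remote zone.

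**Figure D1:**
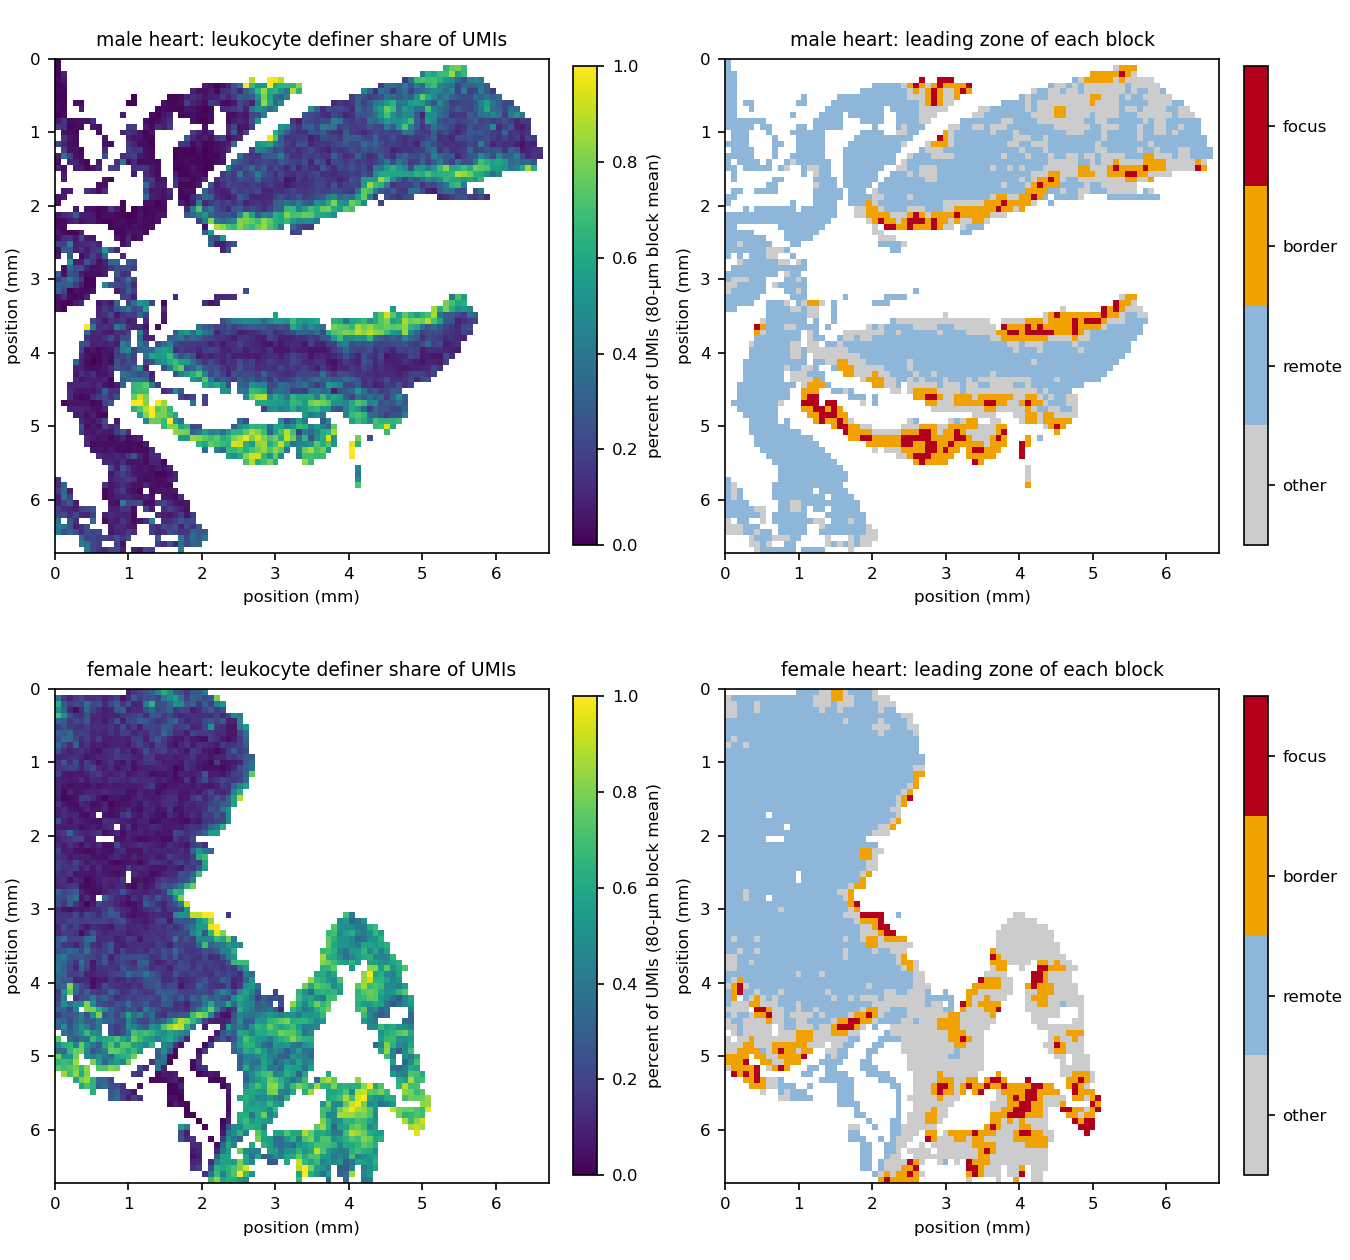
Maps of both sections in 80-µm blocks, with both axes in mm, show the share of UMIs from leukocyte genes (colour, 0 to 1%) and the leading zone of each block. The male section holds 72 focus patches and the female section 83.

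Foci were set against remote tissue to describe what the infiltrates contain and what is lost from the muscle around them. T cell, macrophage and dendritic cell transcripts rose and contractile, electrical and metabolic transcripts of cardiomyocytes fell in both hearts. Cd8a rose by 2.46 ± 0.35 (log2 ± SE, n = 2 hearts; adjusted p = 0.0119, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Cd4 by 2.71 ± 0.34 (adjusted p = 0.00895). Ifng, a cytokine of activated T and NK cells, rose by 3.07 ± 0.30 (adjusted p = 0.00578). Gja1, which encodes the main ventricular gap junction protein, changed by -4.08 ± 0.41 (adjusted p = 0.00591). Of 15324 genes tested, 5995 passed, 2839 higher and 3156 lower. With library sizes only, 6624 were higher and 1797 lower, and the median gene then lay at 0.71 in the focus and 0.67 in the border comparison. Within atrial-class bins only, 0 genes passed by edgeR's quasi-likelihood test and 2598 had an unadjusted p under 0.05; DESeq2 was not run on these bins. In ventricular bins only 8083 genes passed, and without extracardiac bins 7318.

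Among the largest increases in foci, Cd5l, a macrophage scavenger protein, rose by 6.11 ± 0.33, though its value was -0.95 within atrial-class bins and -0.17 with foci set from T cell genes. Ccl22, a chemokine of dendritic cells that attracts regulatory T cells, rose by 4.83 ± 0.28. Ly6i rose by 4.71 ± 0.60, Mcemp1 by 4.68 ± 0.39 and Xcl1, a chemokine of activated CD8 T and NK cells, by 4.46 ± 0.33. Kmo, an enzyme of tryptophan breakdown, rose by 4.24 ± 0.32, the MHC class II chaperone gene H2-Oa by 4.23 ± 0.15, the acute-phase gene Saa3 by 4.13 ± 0.21. The interleukin-2 receptor gene Il2ra rose by 3.85 ± 0.28 and Chil3 by 3.84 ± 0.45. The largest decreases were in Ckm (-7.25 ± 0.44), the lipid droplet gene Plin5 (-7.13 ± 0.34), Car14 (-6.89 ± 0.26), Cyp2f2 (-6.73 ± 0.49), Lrtm1 (-6.56 ± 0.33), Hrc (-6.53 ± 0.42), Tnnc2 (-6.52 ± 0.88), Slc38a3 (-6.48 ± 0.20), Pirt (-6.31 ± 0.25) and Fitm1 (-6.27 ± 0.22). Cyp2f2, an enzyme of airway club cells, stood at 344 CPM in the male and 0.48 CPM in the female remote zone, and its fall was smaller without extracardiac bins (-2.07). Tnnc2 was then at -0.998 and did not pass (adjusted p = 0.163).

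Lymphocyte lists are higher in foci partly by construction, since foci were set from leukocyte genes and remote bins by a low leukocyte share. All 19 T cell genes rose (19 adjusted over the list alone), among them Cd5 by 2.93 ± 0.19 and Lck by 2.73 ± 0.23 (list median 2.71, camera adjusted p = 3.23e-14, adjusted p = 0.506 with an estimated correlation). Of 14 cytotoxic genes 13 rose (13 adjusted over the list alone), with Klrk1 at 2.89 ± 0.21, Gzmk at 2.72 ± 0.26 and Gzmb at 1.96 ± 0.24, and only Gzma did not pass (camera adjusted p = 1.94e-08, adjusted p = 0.549 with an estimated correlation). Of 12 checkpoint and activation genes 11 rose (11 adjusted over the list alone), led by Ctla4 at 3.36 ± 0.15 and Icos at 3.28 ± 0.17 (camera adjusted p = 4.11e-09, adjusted p = 0.506 with an estimated correlation). All 4 regulatory T cell genes rose (4 adjusted over the list alone), with Foxp3 at 3.69 ± 0.27 beside Il2ra (camera adjusted p = 0.000159, adjusted p = 0.467 with an estimated correlation). B and plasma cell genes rose in 6 of 9 cases (7 adjusted over the list alone), with Ighm at 3.04 ± 0.17 and Cd79b at 2.51 ± 0.21, and 3 did not pass (camera adjusted p = 0.000159, adjusted p = 0.467 with an estimated correlation). Of 4 NK cell genes 0 passed (4 adjusted over the list alone), with Klre1 at 1.88 ± 0.51 and Klra8 at 1.89 ± 0.51 (camera adjusted p = 0.172). Of 5 thymocyte and lymph node genes only Rag1 rose, at 2.14 ± 0.54, and Cxcl13 at 2.80 ± 0.85 did not pass (0 adjusted over the list alone, camera adjusted p = 0.286).

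Myeloid genes rose too, and here again the direction follows partly from how foci were set. All 12 macrophage genes rose (12 adjusted over the list alone), with the Fc receptor gene Fcgr1 at 2.72 ± 0.17 and the integrin gene Itgam at 2.39 ± 0.15 (camera adjusted p = 1.39e-10, adjusted p = 0.467 with an estimated correlation). All 7 monocyte-derived genes rose (7 adjusted over the list alone), with Ccr2 at 2.80 ± 0.14 and Spp1 at 2.20 ± 0.18 (camera adjusted p = 2.63e-06, adjusted p = 0.467 with an estimated correlation). Within atrial-class bins Spp1 was at -0.19. Of 8 dendritic cell genes 7 rose (7 adjusted over the list alone), with Clec9a, a mark of cross-presenting cells, at 2.99 ± 0.25 and Flt3 at 3.81 ± 0.33 (camera adjusted p = 5.97e-05, adjusted p = 0.467 with an estimated correlation). Neutrophil genes rose in 5 of 7 cases (6 adjusted over the list alone), with S100a9 at 3.58 ± 0.14 and Csf3r at 3.34 ± 0.15 (camera adjusted p = 1.53e-06, adjusted p = 0.467 with an estimated correlation). With foci set from T cell genes the neutrophil list turned to -1.23 and S100a9 to -1.41. Of 5 mast cell genes only Kit passed, at 2.15 ± 0.24, and Cma1 was at 0.82 ± 0.67 (1 adjusted over the list alone, camera adjusted p = 0.387). Of 7 resident macrophage genes only Mrc1 rose, at 0.90 ± 0.23, and Cbr2 at -3.54 ± 1.60 did not pass (0 adjusted over the list alone, camera adjusted p = 0.844).

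MHC class II and most chemokine genes rose, while MHC class I and interferon response genes were mixed. All 7 MHC class II genes rose (7 adjusted over the list alone), with H2-DMa at 2.05 ± 0.19 and the class II transactivator gene Ciita at 2.04 ± 0.21 (camera adjusted p = 7.03e-05, adjusted p = 0.549 with an estimated correlation). Of 15 chemokine genes 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Ccl22 and Ccl8 (2.42 ± 0.16) higher and Cxcl12, which homes leukocytes to stroma, at -0.60 ± 0.14 (camera adjusted p = 8.57e-07, adjusted p = 0.506 with an estimated correlation). With library sizes only Cxcl12 was at 0.0738, so its call rests on the scaling. The interferon-inducible chemokine genes Cxcl9 and Cxcl10 rose by 2.12 ± 0.29 and 1.98 ± 0.19. Of 10 inflammasome and cytokine genes 9 rose (9 adjusted over the list alone), with the pore-forming Gsdmd at 2.09 ± 0.13 and Casp1 at 2.05 ± 0.19 (camera adjusted p = 1.7e-06, adjusted p = 0.467 with an estimated correlation). Of 18 interferon-gamma response genes 9 rose, 3 fell and 6 did not pass (10 and 5 adjusted over the list alone), with Gbp5 at 1.51 ± 0.14 higher beside Cxcl10, and Gbp6 at -1.49 ± 0.22, Igtp at -1.34 ± 0.24 and Irgm1 at -1.48 ± 0.39 lower (camera adjusted p = 0.0886). Within atrial-class bins Gbp6 was at 0.51, Igtp at 0.74 and Irgm1 at 0.69. Of type I interferon genes, Oasl2 at 0.83 ± 0.13 and Ifit3 at -0.65 ± 0.16 were the called members of 9 (1 and 0 adjusted over the list alone, camera adjusted p = 0.929), and the list's median of -0.12 changed sign with library sizes only. Ifit3 was then at 0.0297, so its call rests on the scaling, and within atrial-class bins it was at 0.56. Of 10 MHC class I genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Nlrc5 at 1.21 ± 0.21 and the immunoproteasome gene Psmb10 at -1.16 ± 0.24 (camera adjusted p = 0.216). Within atrial-class bins Psmb10 was at 0.64. Proliferation genes rose in 6 of 8 cases (7 adjusted over the list alone), with Mki67 at 1.77 ± 0.24 and Top2a at 1.86 ± 0.26 (camera adjusted p = 0.0111, adjusted p = 0.682 with an estimated correlation).

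Cardiomyocyte genes fell across contraction, conduction and metabolism, which also follows partly from how foci were set. A share of leukocyte UMIs among all UMIs favours bins with few cardiomyocyte UMIs. All 15 contractile reference genes fell (15 adjusted over the list alone), with Cmya5 at -4.55 ± 0.23 and Ldb3 at -4.43 ± 0.24 (camera adjusted p = 1.58e-20, adjusted p = 0.467 with an estimated correlation). Of 24 ion channel genes 19 fell and 5 did not pass (21 adjusted over the list alone), with the potassium channel genes Kcnk3 at -4.94 ± 0.15 and Kcnj11 at -5.05 ± 0.16 (camera adjusted p = 3.79e-18, adjusted p = 0.467 with an estimated correlation). Intercalated disc genes fell in 10 of 11 cases (10 adjusted over the list alone), with the desmosome genes Dsc2 at -4.82 ± 0.17 and Pkp2 at -3.78 ± 0.15 (camera adjusted p = 4.37e-12, adjusted p = 0.467 with an estimated correlation). Of 11 calcium handling genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with Casq2 at -4.82 ± 0.25 and Trdn at -3.73 ± 0.19 lower and Fkbp1b at 1.32 ± 0.33 higher (camera adjusted p = 3.7e-10, adjusted p = 0.496 with an estimated correlation). Conduction system genes fell in 5 of 10 cases (5 adjusted over the list alone), with Tbx3 at -2.44 ± 0.20 and Irx3 at -4.46 ± 0.40 (camera adjusted p = 0.0156, adjusted p = 0.589 with an estimated correlation). All 3 ventricular genes fell (3 adjusted over the list alone), with Irx4 at -5.74 ± 0.42 and Myl3 at -6.07 ± 0.63 (camera adjusted p = 0.000195, adjusted p = 0.506 with an estimated correlation). Of 5 atrial genes 0 passed (0 adjusted over the list alone), with Dkk3 at -0.77 ± 1.19 and Bmp10 at -2.48 ± 6.65 (camera adjusted p = 0.894).

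All 15 oxidative phosphorylation genes fell (15 adjusted over the list alone), with Atp5a1 at -2.87 ± 0.14 and Cox8b at -5.78 ± 0.30 (camera adjusted p = 5.18e-17, adjusted p = 0.506 with an estimated correlation). All 15 fatty acid oxidation genes fell too (15 adjusted over the list alone), with Ppara at -4.66 ± 0.18 and its coactivator Ppargc1a at -5.55 ± 0.24 (camera adjusted p = 6.08e-16, adjusted p = 0.467 with an estimated correlation). Of 12 cardiac stress genes 7 fell and 2 rose (9 and 2 adjusted over the list alone). The natriuretic peptide gene Nppb fell by 4.31 ± 0.43, Nmrk2 by 4.60 ± 0.28 and Acta1 by 5.86 ± 0.55, while heme oxygenase, Hmox1, rose by 1.88 ± 0.20 and Atf3 by 0.67 ± 0.13 (camera adjusted p = 0.00108, adjusted p = 0.481 with an estimated correlation). Nppa, at -3.97 ± 1.12, did not pass (adjusted p = 0.0583).

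Among stromal lists, most vessel genes fell, while some activation and matrix genes rose. Of 8 endothelial genes 7 fell (8 adjusted over the list alone), with the VEGF receptor gene Kdr at -2.13 ± 0.15 and Tie1 at -1.72 ± 0.14 (camera adjusted p = 4.67e-05, adjusted p = 0.467 with an estimated correlation). Of 6 endothelial activation genes 3 rose (3 adjusted over the list alone), with the adhesion genes Icam1 at 1.80 ± 0.15 and Selp at 2.16 ± 0.20 (camera adjusted p = 0.0583). With foci set from T cell genes Selp was at -0.97. Matrix remodelling genes rose in 4 of 12 cases (5 adjusted over the list alone), with the collagen cross-linking gene Lox at 1.18 ± 0.13 and Fn1 at 1.37 ± 0.20 (camera adjusted p = 0.0701), though within atrial-class bins Lox was at -0.19 and Fn1 at -0.40. Of 8 fibroblast genes only Pi16 passed, at -1.25 ± 0.13, and Tcf21 was at 1.37 ± 0.66 (1 adjusted over the list alone, camera adjusted p = 0.929), with a list median of 0.06 and a camera direction of down. Mural genes fell in 3 of 8 cases (4 adjusted over the list alone), with Cnn1 at -3.98 ± 0.29 and Myh11 at -3.15 ± 0.31 (camera adjusted p = 0.013, adjusted p = 0.506 with an estimated correlation). Of 6 epicardial genes only Wt1 fell, at -2.48 ± 0.30, and Krt19 at -2.94 ± 1.37 did not pass (1 adjusted over the list alone, camera adjusted p = 0.273). All 7 adipocyte genes fell (7 adjusted over the list alone), with Adipoq at -4.85 ± 0.32 and Cidec at -5.09 ± 0.47 (camera adjusted p = 7.03e-05, adjusted p = 0.467 with an estimated correlation). Of 5 blood genes 4 fell (4 adjusted over the list alone), with Hbb-bt at -2.93 ± 0.18 and Hba-a2 at -2.59 ± 0.17 (camera adjusted p = 0.000195, adjusted p = 0.549 with an estimated correlation), and without the density mask the list's value was 0.35, that of Hbb-bt 0.0592 and that of Hba-a2 0.40. Of 5 Schwann and nerve genes 0 passed (0 adjusted over the list alone), with Gfra3 at 0.47 ± 0.82 and S100b at -0.20 ± 0.43 (camera adjusted p = 0.952). The list median of -0.20 changed sign with library sizes only and camera's direction was up. By camera 26 of 39 lists passed, while with an estimated correlation and with fry 0 passed. With 1 residual degree of freedom per gene, these last 2 tests have little power and do not decide about a list.

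**Figure D2:**
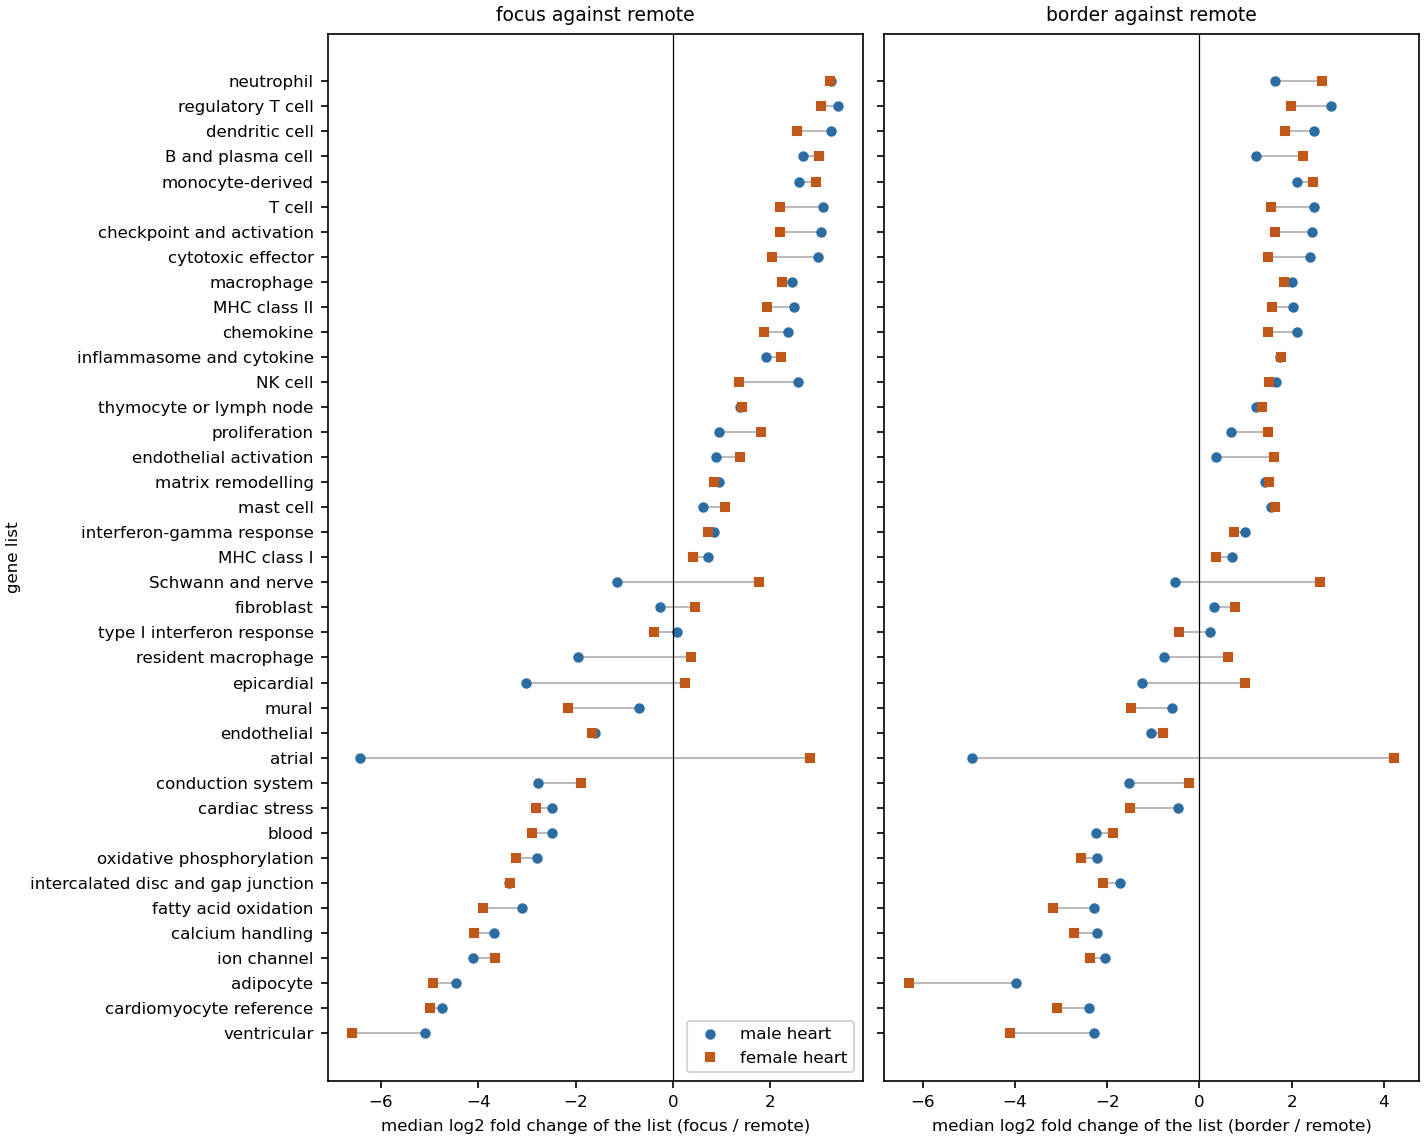
Median log2 fold change of each gene list in focus (left) and border (right) against remote tissue, with 1 point per heart. T cell genes have a fitted median of 2.71 in foci and 2.07 in borders, contractile genes of -4.79 and -2.88, and the atrial list lies on opposite sides of 0 in the hearts.

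Borders were set against remote tissue to describe what lies beside a focus. Many immune transcripts rose and many cardiomyocyte transcripts fell in the border as well. The direction follows partly from how zones were set, since border bins lie beside leukocyte-rich bins. Remote bins lie away from them and were also set by a low leukocyte share. Bins outside the kept tissue and within 50 µm of it also held UMIs, and whether RNA of foci reached border bins was not tested. Ctla4 rose by 2.66 ± 0.17, Ifng by 2.45 ± 0.24 (adjusted p = 0.0098), Cd4 by 2.07 ± 0.46 (adjusted p = 0.0487) and Cd8a by 1.87 ± 0.29 (adjusted p = 0.021), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cxcl9 rose by 1.71 ± 0.31, Cxcl10 by 1.59 ± 0.26 and Gzmb by 1.48 ± 0.23. Gja1 was at -2.20 ± 0.37 (adjusted p = 0.0247) and Nppb at -2.19 ± 0.35, while Nppa at -2.26 ± 1.01 did not pass (adjusted p = 0.162). Of 15301 genes tested, 4446 passed, 2067 higher and 2379 lower, against 5769 higher and 1237 lower with library sizes only. Within atrial-class bins 0 genes passed by edgeR's quasi-likelihood test and 1139 had an unadjusted p under 0.05. In ventricular bins only 7447 genes passed, and against remote bins matched on cardiomyocyte share 2387 passed. The match was partial. The contractile reference took 2.17% of UMIs in the drawn female remote bins against 1.49% in the border, and 1.58% against 1.38% in the male heart.

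The largest border increases were in Cd5l (5.69 ± 1.05; 50.1 CPM in the female and 0.658 CPM in the male border), Chil3 (3.31 ± 0.61), H2-Oa (3.25 ± 0.18), the stress-induced gene Sprr1a (3.22 ± 0.21), Saa3 (3.15 ± 0.16), Cd300lf (3.03 ± 0.17), Foxp3 (2.98 ± 0.25), Igkc (2.91 ± 0.52), the activin inhibitor gene Fst (2.88 ± 0.26) and Plac8 (2.82 ± 0.32). The largest decreases were in Cyp2f2 (-6.65 ± 0.40), Pck1 (-5.73 ± 0.88), Scd4 (-5.48 ± 0.17), Car3 (-5.46 ± 0.90), Cfd (-5.36 ± 0.93), Ces1d (-5.03 ± 0.37), Ltf (-4.90 ± 0.92), Ckm (-4.81 ± 0.52) and Lrtm1 (-4.73 ± 0.60). The airway gene Cyp2f2 stood at 344 CPM in the remote zone and 4.53 CPM in the border of the male heart. In the female heart it stood at only 0.480 and 0.0618 CPM. In ventricular bins only, Ltf was at 0.61 and Cd5l within atrial-class bins was at -1.03.

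All 19 T cell genes rose in the border (19 adjusted over the list alone), with Trbc1 at 2.12 ± 0.24. Cytotoxic genes rose in 12 of 14 cases (13 adjusted over the list alone), with Prf1 at 2.10 ± 0.20 and Klrk1 at 2.25 ± 0.21. Checkpoint genes rose in 11 of 12 (11 adjusted over the list alone), with Icos at 2.65 ± 0.15 beside Ctla4. All 4 regulatory T cell genes rose (4 adjusted over the list alone), with Il10 at 2.16 ± 0.35 beside Foxp3. So did 4 of 9 B and plasma cell genes (4 adjusted over the list alone), with Ighm at 2.41 ± 0.17 and Cd79b at 1.73 ± 0.22. All 12 macrophage genes rose (12 adjusted over the list alone), with Itgam at 2.01 ± 0.14 and the lipid-sensing receptor gene Trem2 at 2.65 ± 0.18. Of 7 monocyte-derived genes 5 rose (7 adjusted over the list alone), with Ccr2 at 2.36 ± 0.14 and Spp1 at 2.21 ± 0.19, though within atrial-class bins Spp1 was at -0.52. Of 8 dendritic cell genes 7 rose (7 adjusted over the list alone), with Itgax at 2.17 ± 0.22 and Clec9a at 2.28 ± 0.26. Of 6 neutrophil genes 3 rose (5 adjusted over the list alone), with Csf3r at 2.61 ± 0.15 and S100a8 at 2.35 ± 0.28, though with zones set from T cell genes S100a8 was at -0.73. Camera's adjusted p ran from 1.07e-12 for macrophages and 1.17e-12 for T cells to 0.00207 for regulatory T cells, each with adjusted p = 0.56 with an estimated correlation. Of 4 NK cell genes 0 passed, with Klra8 at 1.83 ± 0.51 and Klre1 at 1.29 ± 0.39 (0 adjusted over the list alone, camera adjusted p = 0.173). Of 5 mast cell genes only Kit passed, at 1.71 ± 0.24, with Cpa3 at 1.62 ± 0.51 (1 adjusted over the list alone, camera adjusted p = 0.243). Of 3 lymph node genes 0 passed, with Cxcl13 at 2.69 ± 0.94 and Fcer2a at 0.95 ± 0.54 (0 adjusted over the list alone, camera adjusted p = 0.308). Of 7 resident macrophage genes only Mrc1 rose, at 0.98 ± 0.15, with Cbr2 at -3.37 ± 1.54 (1 adjusted over the list alone, camera adjusted p = 0.965). Its median of -0.38 changed sign with library sizes only.

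Chemokine genes rose in 11 of 15 cases in the border (14 adjusted over the list alone), with the endothelial chemokine gene Cx3cl1 at 2.31 ± 0.13 and Ccl8 at 2.03 ± 0.17 (camera adjusted p = 2.4e-09, adjusted p = 0.56 with an estimated correlation). Of 18 interferon-gamma response genes 8 rose and 0 fell (9 and 1 adjusted over the list alone), with Gbp5 at 1.32 ± 0.14 and Socs1 at 1.40 ± 0.18 (camera adjusted p = 0.0141, adjusted p = 0.696 with an estimated correlation). Of 9 type I interferon genes only Oasl2 passed, at 0.81 ± 0.13, with Ifi44 at 0.54 ± 0.19 (1 adjusted over the list alone, camera adjusted p = 0.965), and the median of -0.15 changed sign with library sizes only. For the type I interferon and the resident macrophage lists camera's direction was up, against the sign of the median. MHC class II genes rose in 4 of 7 cases (7 adjusted over the list alone), with H2-DMa at 1.69 ± 0.19 and Ciita at 1.62 ± 0.20 (camera adjusted p = 3.16e-05, adjusted p = 0.56 with an estimated correlation). MHC class I genes rose in 2 of 10 (0 adjusted over the list alone), with Nlrc5 at 1.01 ± 0.23 and Tap1 at 0.93 ± 0.23 (camera adjusted p = 0.14). Of 10 inflammasome genes 8 rose (10 adjusted over the list alone), with Gsdmd at 1.69 ± 0.13 and Pycard at 1.61 ± 0.16 (camera adjusted p = 2.54e-07, adjusted p = 0.56 with an estimated correlation). Of 8 proliferation genes 2 rose (6 adjusted over the list alone), Mki67 at 1.28 ± 0.18 and Top2a at 1.39 ± 0.25 (camera adjusted p = 0.0158, adjusted p = 0.619 with an estimated correlation). Matrix remodelling genes rose in 6 of 12 cases (9 adjusted over the list alone), with Lox at 1.84 ± 0.15 and Timp1 at 2.16 ± 0.31 (camera adjusted p = 8.94e-05, adjusted p = 0.56 with an estimated correlation). Of 6 endothelial activation genes 2 rose (2 adjusted over the list alone), Icam1 at 1.61 ± 0.14 and Vcam1 at 1.81 ± 0.21 (camera adjusted p = 0.0388, adjusted p = 0.657 with an estimated correlation).

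Contractile genes fell in 14 of 15 cases in the border (15 adjusted over the list alone), with Cmya5 at -2.96 ± 0.21 beside Ckm (camera adjusted p = 1.45e-14). Ion channel genes fell in 20 of 24 (20 adjusted over the list alone), with Kcnj11 at -3.22 ± 0.15 and Kcnq1 at -2.75 ± 0.14 (camera adjusted p = 1.77e-16). Intercalated disc genes fell in 9 of 11 (10 adjusted over the list alone), with Dsc2 at -3.24 ± 0.14 and Ctnna3 at -2.54 ± 0.14 (camera adjusted p = 2.84e-09). Calcium handling genes fell in 9 of 11 (9 lower and 1 higher adjusted over the list alone), with Hrc at -4.31 ± 0.26 and Trdn at -2.38 ± 0.22 (camera adjusted p = 3.52e-09). All 15 oxidative phosphorylation genes fell (15 adjusted over the list alone), with Atp5a1 at -2.41 ± 0.16 and Ndufs1 at -2.38 ± 0.19 (camera adjusted p = 1.46e-16). All 15 fatty acid oxidation genes fell (15 adjusted over the list alone), with Ppargc1a at -3.22 ± 0.16 and Ppara at -3.18 ± 0.17 (camera adjusted p = 4.46e-17). All 3 ventricular genes fell (3 adjusted over the list alone), with Irx4 at -2.77 ± 0.44 and Myl3 at -3.44 ± 0.77 (camera adjusted p = 0.00679). For each of these lists adjusted p = 0.56 with an estimated correlation. Against remote bins matched on cardiomyocyte share Trdn was at 0.09 and Irx4 at 0.98.

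Conduction system genes fell in 4 of 11 cases in the border (4 adjusted over the list alone), with Tbx3 at -1.84 ± 0.29 and Hcn4 at -1.74 ± 0.29 (camera adjusted p = 0.0537), though within atrial-class bins Hcn4 was at 0.65. Of 12 cardiac stress genes 2 rose and 2 fell (2 and 4 adjusted over the list alone), with Hmox1 at 1.79 ± 0.26 higher and Nppb lower (camera adjusted p = 0.129). Endothelial genes fell in 5 of 8 cases (7 adjusted over the list alone), with Kdr at -1.49 ± 0.14 and Fabp4 at -2.06 ± 0.28 (camera adjusted p = 0.000751, adjusted p = 0.56 with an estimated correlation). Of 8 mural genes 2 fell and 1 rose (5 and 2 adjusted over the list alone), with Cnn1 at -2.47 ± 0.29 and Acta2 at -1.11 ± 0.22 lower and Notch3 at 0.62 ± 0.13 higher (camera adjusted p = 0.144). Against matched remote bins Notch3 was at -0.22. Of 8 fibroblast genes only Pdgfra rose, at 0.84 ± 0.17, with Lum at 0.74 ± 0.19 (0 adjusted over the list alone, camera adjusted p = 0.294). Against matched remote bins they were at -0.52 and -1.005. Of 6 epicardial genes only Wt1 fell, at -1.33 ± 0.26, with Krt19 at -2.14 ± 1.10 (1 adjusted over the list alone, camera adjusted p = 0.646). Adipocyte genes fell in 6 of 7 cases (7 adjusted over the list alone), with Ucp1 at -5.13 ± 0.47 and Cidec at -4.73 ± 0.63 (camera adjusted p = 5.97e-05, adjusted p = 0.56 with an estimated correlation). Blood genes fell in 4 of 5 (4 adjusted over the list alone), with Hbb-bt at -2.30 ± 0.14 and Hba-a2 at -2.02 ± 0.18 (camera adjusted p = 6.73e-05, adjusted p = 0.56 with an estimated correlation), and without the density mask the list's value was 0.30 and that of Hba-a2 0.40. Of 5 Schwann and 5 atrial genes 0 passed (0 adjusted over either list alone), with Gfra3 at 1.38 ± 0.96, Sox10 at 1.11 ± 1.00, Dkk3 at -0.25 ± 1.46 and Bmp10 at -1.80 ± 11.1 (camera adjusted p = 0.696 and 0.965). The medians of the epicardial list (-0.21) and of the atrial list (-0.25) changed sign with library sizes only. By camera 26 of 39 lists passed, and 0 with an estimated correlation or with fry.

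Levels by distance from a focus show how each signal changes away from the infiltrate, as values per heart without a test. T cell genes went from 3158 CPM in foci to 444 CPM beyond 400 µm in the male heart and from 2635 to 491 CPM in the female heart. MHC class II genes went from 54011 to 9871 CPM and from 43320.5 to 7680 CPM. In the male heart the interferon-gamma response list stood at 11805 CPM in foci, 12274 CPM within 50 µm, 11499 CPM at 100 to 200 µm and 5638 CPM beyond 400 µm. In the female heart it stood at 10901 CPM within 50 µm, 9218 CPM at 100 to 200 µm and 6448 CPM beyond 400 µm. MHC class I genes went from 8753 to 4035 CPM and from 8202 to 4452 CPM. Matrix remodelling genes stood at 9181 CPM within 50 µm against 6792 CPM in male foci. In the female heart they stood at 14498 CPM at 100 to 200 µm, a different distance, against 7515 CPM in foci. Beyond 400 µm they were lower, at 2944 and 2555 CPM. The female atrial class carried 18219 CPM of matrix genes and the ventricular class 2723 CPM, so distance and anatomy are not told apart there. Contractile genes went from 3572 CPM in foci to 52240 CPM beyond 400 µm in the male heart and from 4848 to 78541 CPM in the female heart. Fatty acid oxidation genes went from 1458 to 9875 and from 1247 to 15548 CPM. In both hearts 21 lists were higher and 13 lower in foci than beyond 400 µm. The Schwann, atrial, epicardial, fibroblast and resident macrophage lists took opposite directions in the hearts. In ventricular bins only, most of them did not. There the log2 ratio, male then female, was 0.40 and 2.12 for Schwann genes and -0.90 and -1.65 for epicardial genes. It was 0.26 and 1.90 for fibroblast genes and 0.14 and 1.33 for resident macrophage genes. Atrial genes stayed opposite, at -0.33 and 2.66.

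**Figure D3:**
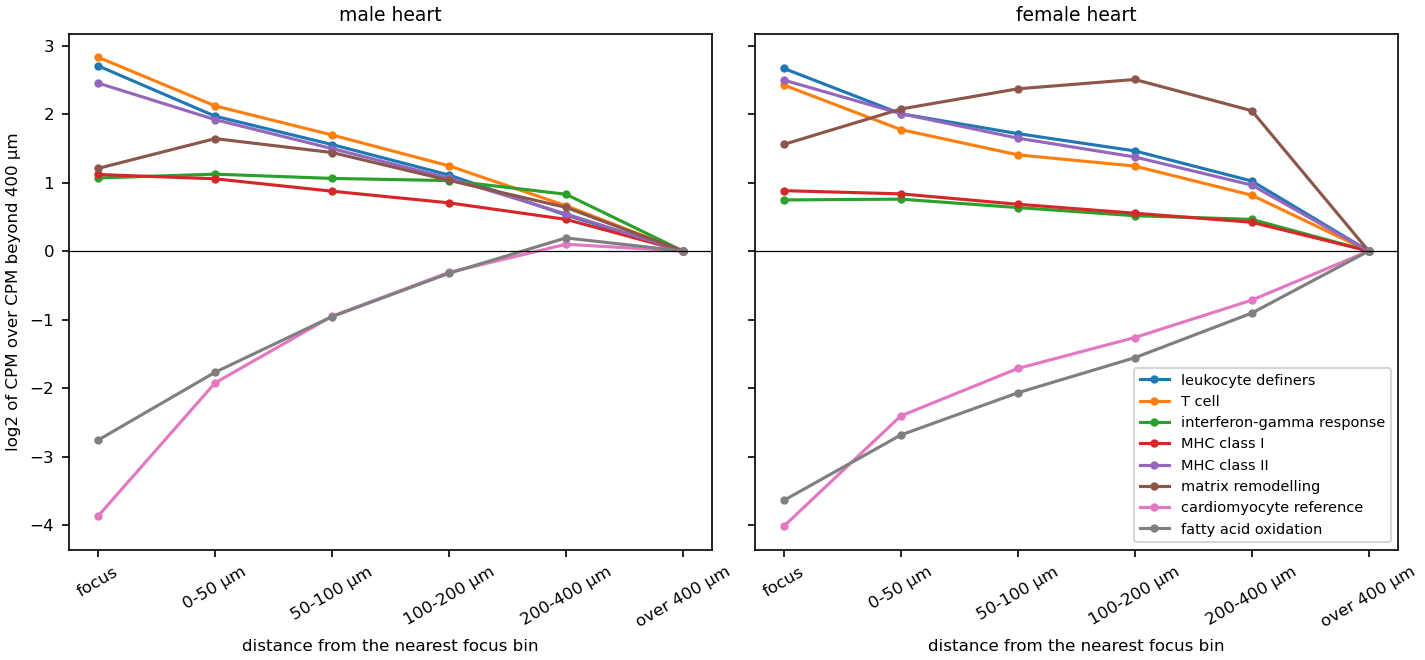
Levels of 8 gene lists by distance from the nearest focus (x axis, µm), as log2 of CPM over CPM beyond 400 µm, with a line per heart. In the male heart T cell genes go from 3158 to 444 CPM, while matrix remodelling genes lie higher within 50 µm of a focus (9181 CPM) than in it (6792 CPM).

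Since foci hold fewer cardiomyocyte transcripts, cardiac lists were also divided by the contractile reference, which asks whether electrical and metabolic genes fell more or less than contractile genes. All 6 lists stood higher in foci than in remote tissue in both hearts on this scale. Relative to the reference, ion channel genes were higher in foci than in remote tissue by 1.87 ± 0.04 (mean log2 ± SD, n = 2), intercalated disc genes by 1.68 ± 0.28 and oxidative phosphorylation genes by 1.47 ± 0.03. Calcium handling genes stood at 0.71 ± 0.08, fatty acid oxidation genes at 0.75 ± 0.48 and cardiac stress genes at 1.40 ± 1.12, the last with 0.61 in the male and 2.19 in the female heart. In atrial-class bins the mean was 1.14 for ion channel genes (female 0.47), 0.90 for disc genes (female 0.0547) and 0.0974 for stress genes. In the border, ion channel genes were at 0.82 in the male and 1.15 in the female heart. Disc genes were at 1.03 in both, oxidative phosphorylation genes at 0.30 and 0.39, and stress genes at 0.14 and 1.74. Calcium handling genes (-0.06 and 0.20) and fatty acid oxidation genes (0.13 and -0.26) took opposite directions there. These lists are also expressed outside cardiomyocytes in part, and these values were not tested.

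The title of the series names CD8 T cells, and bins of foci with CD8 transcripts were therefore set against those with Cd4. Some cytotoxic, chemokine and contractile genes were higher in CD8 bins, and some regulatory T cell and matrix genes and the B cell gene Ighm in CD4 bins. Lists were not tested here. Xirp2, a stress-responsive muscle gene, was higher in CD8 bins by 1.46 ± 0.18 (adjusted p = 3.75e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Tnnt2 by 0.73 ± 0.09 (adjusted p = 1.48e-07) and Ccl5 by 0.69 ± 0.08 (adjusted p = 1.01e-07). Foxp3, the regulatory T cell factor, was at -1.77 ± 0.26 (adjusted p = 1.57e-05), and Ighm was at -0.87 ± 0.11 (adjusted p = 3.89e-07). The comparison held 3647 CD8 and 357 CD4 bins in the male heart and 3081 and 326 in the female heart, with median UMIs of 707 and 629 and of 893 and 865. All CD4 bins together held only 235474 UMIs in the male and 281195 in the female heart. Of 10873 genes tested, 59 passed, 36 higher and 23 lower, and DESeq2 called 12, 10 higher and 2 lower. Without the heart as a block 0 genes passed by edgeR's quasi-likelihood test and 408 had an unadjusted p under 0.05.

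Further genes higher in CD8 bins were Tmod1 (1.82 ± 0.44), Enah (1.79 ± 0.41), Glp1r (1.495 ± 0.30), Tcrg-C2 (1.42 ± 0.35), Nrn1 (1.21 ± 0.22), Mylk3 (1.19 ± 0.28), Ifng (1.14 ± 0.24), the chemokine genes Ccl3 (1.11 ± 0.17) and Ccl4 (0.92 ± 0.15) and the perforin gene Prf1 (1.04 ± 0.21). Few UMIs carried the first of these in CD4 bins. There, male then female, Tmod1 stood at 12.7 and 14.2 CPM and Enah at 17.0 and 14.2 CPM. Of 14 cytotoxic genes 5 were higher (7 adjusted over the list alone), among them Prf1 and Nkg7 (0.90 ± 0.13), while Gzmb at 1.29 ± 0.36 did not pass (adjusted p = 0.113). Of 15 contractile genes 5 were higher (8 higher and 1 lower adjusted over the list alone), among them Tnnt2 and Myom2 (0.89 ± 0.19). Of 12 cardiac stress genes 2 were higher (4 adjusted over the list alone), Xirp2 and Ankrd1 (0.82 ± 0.10). Of 9 intercalated disc genes only Dsp passed (0.97 ± 0.24; 1 adjusted over the list alone), and of 5 atrial genes only Bmp10 (0.96 ± 0.23; 1 adjusted over the list alone), which was at -0.31 in the male heart. Checkpoint genes split, with Lag3 (0.88 ± 0.17) and Havcr2 (0.62 ± 0.15) higher and Ctla4 (-0.76 ± 0.19) lower of 12 (4 and 1 adjusted over the list alone). Of 14 chemokine genes 3 were higher and Ccl19 was lower (-0.79 ± 0.18; 5 and 3 adjusted over the list alone). Lower genes also included Ikzf2 (-1.43 ± 0.26), Shmt2 (-1.30 ± 0.33), Penk (-1.23 ± 0.25), the costimulatory receptor gene Tnfrsf4 (-1.15 ± 0.20), Mtmr12 (-1.04 ± 0.26), Sfrp2 (-0.96 ± 0.24) and Fbln1 (-0.81 ± 0.15). Of 4 regulatory T cell genes 2 were lower, Foxp3 and Ikzf2 (2 adjusted over the list alone). Of 7 B and plasma cell genes only Ighm was lower (4 adjusted over the list alone), and of 11 matrix genes Col3a1 (-0.43 ± 0.08) and Col1a1 (-0.36 ± 0.08; 1 higher and 3 lower adjusted over the list alone). Of 17 interferon-gamma response genes 0 passed (7 adjusted over the list alone), with Cxcl9 at 0.25 ± 0.08 and Cxcl10 at 0.45 ± 0.17, and Gja1 (0.04 ± 0.46), Nppa (0.41) and Nppb (0.31) did not pass. In all, 10 of 37 lists held a called gene.

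**Figure D4:**
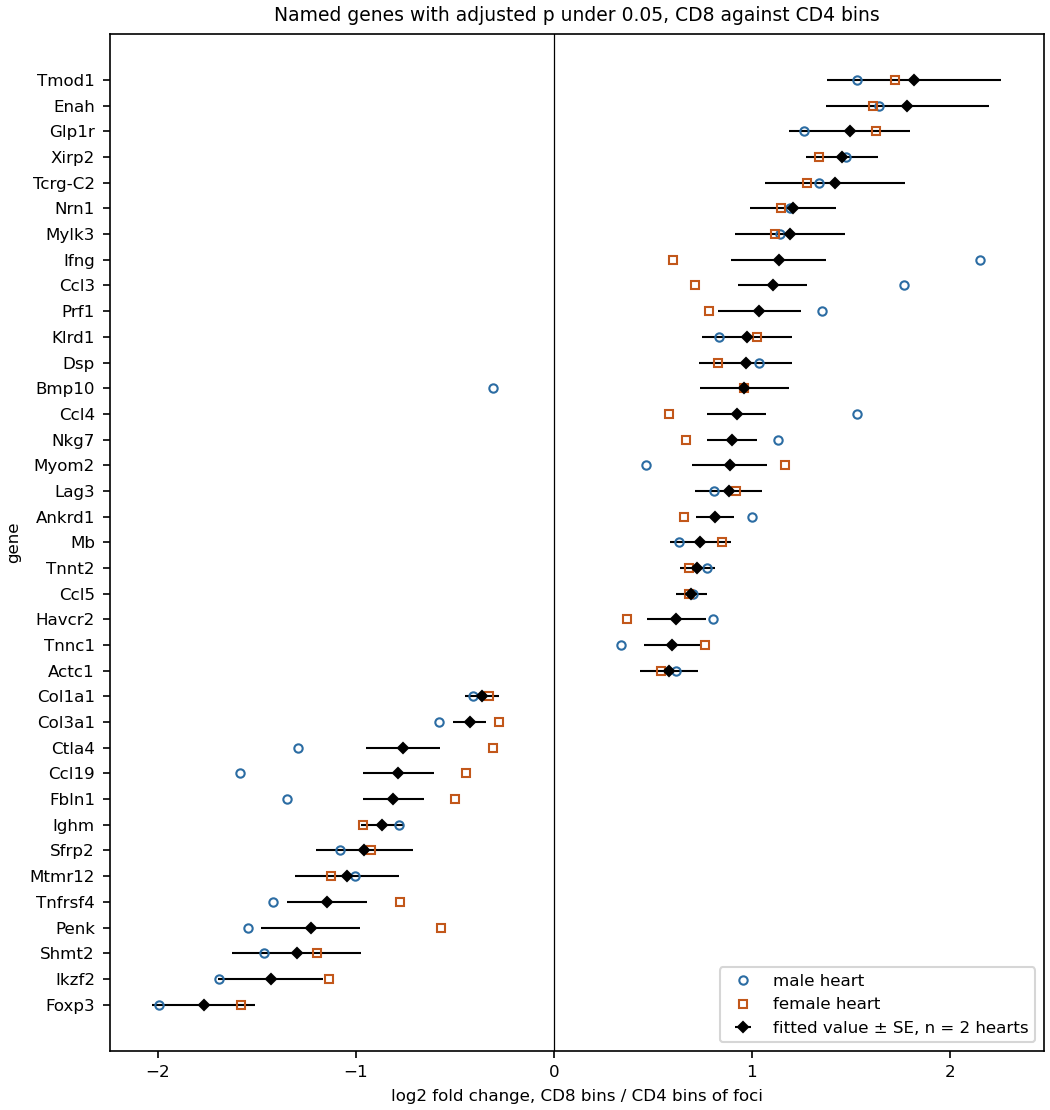
Log2 fold change of called genes between CD8 and CD4 bins of foci (x axis), with the fitted value ± SE as a bar and 1 point per heart. Per-heart values were computed apart from the fit; Xirp2 lies at 1.46 and Foxp3 at -1.77.

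The surroundings of these bins were compared to ask what lies near CD8 signal without Cd4 signal, and near Cd4 signal without CD8 signal. Some chemokine, interferon-induced and muscle stress genes were higher near CD8 signal, and some immunoglobulin and stromal genes near CD4 signal. Lists were not tested here either. Xirp2 was higher near CD8 bins by 1.40 ± 0.19 (adjusted p = 1.28e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Cxcl9 by 0.70 ± 0.13 (adjusted p = 6.08e-05) and Ccl4 by 1.18 ± 0.23 (adjusted p = 0.000215). Igkc was at -1.15 ± 0.12 (adjusted p = 2.92e-19), and Ifng at 1.13 ± 0.38 did not pass (adjusted p = 0.201). The comparison held 11017 and 544 bins in the male heart and 8550 and 368 in the female heart. The CD4 neighbourhoods held only 223839 UMIs in the male and 187874 in the female heart. A few UMIs thus set the level of a rare gene there. CD8 bins made up 26.7% of the bins in male foci and 26.9% in female foci. Neighbourhoods of CD4 bins had to lie away from all of them, and so in CD8-poor spots. Whether differences between the neighbourhoods reflect this choice of spots was not tested. Of 11914 genes tested, 77 passed, 34 higher and 43 lower, against 23 higher and 50 lower with library sizes only. DESeq2 called 16, 5 higher and 11 lower, and without the heart as a block 0 genes passed by edgeR's quasi-likelihood test and 469 had an unadjusted p under 0.05.

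Other genes higher near CD8 bins were Mad2l1bp (2.45 ± 0.64), Nudt18 (2.12 ± 0.58), Nes (1.76 ± 0.46), Ociad1 (1.44 ± 0.38), Serpinb1a (1.39 ± 0.37), AA467197 (1.29 ± 0.22), Uchl1 (1.15 ± 0.23), Acta1 (1.12 ± 0.31) and Ccl3 (1.11 ± 0.26), though with all kept tissue Ociad1 was at -0.04 and with 16-µm bins Acta1 was at -0.26. The first of these rest on few UMIs near CD4 bins. There, male then female, Mad2l1bp stood at 4.47 and 10.6 CPM, Nudt18 at 13.4 and 5.32 and Nes at 22.3 and 10.6. Of 15 chemokine genes 4 were higher and Cxcl12 was lower (-0.79 ± 0.20; 6 and 2 adjusted over the list alone). Of 18 interferon-gamma response genes 3 were higher (7 adjusted over the list alone), Cxcl9, Serpina3g (0.54 ± 0.13) and Gbp2 (0.49 ± 0.13). Of 10 MHC class I genes Psmb8 was higher (0.53 ± 0.15; 2 adjusted over the list alone). Of 12 cardiac stress genes 3 were higher, Xirp2, Acta1 and Ankrd1 (0.61 ± 0.12; 5 higher and 1 lower adjusted over the list alone). Of 15 contractile genes 2 were higher, Myom2 (0.66) and Tnnt2 (0.44; 4 adjusted over the list alone). Ccl5 (0.56 ± 0.12), S100a9 (1.02 ± 0.28) and Dsp (0.84 ± 0.23) passed as well. Male S100a9 stood at only 8.35 CPM near CD8 bins and at 4.47 CPM near CD4 bins. Lower genes were Cyp2e1 (-4.56 ± 1.00), Car3 (-4.25 ± 0.57), Iglc1 (-3.58 ± 0.28), Cfd (-3.42 ± 0.78), Ighg2b (-2.93 ± 0.16), Cd79a (-1.89 ± 0.48), Igf2 (-1.80 ± 0.41), Plagl1 (-1.77 ± 0.47), Cd79b (-1.60 ± 0.33) and Vegfd (-1.38 ± 0.24). In the female heart Cyp2e1, Car3 and Cfd each stood at only 5.32 CPM near CD4 bins. With all kept tissue Ighg2b no longer passed (adjusted p = 0.612) and Plagl1 was at 0.0642. Of 8 B and plasma cell genes 4 were lower (6 adjusted over the list alone), among them Ighm (-0.96 ± 0.15), whose value in the female heart was 0.02. Of 8 fibroblast genes 2 were lower, Gsn (-0.65 ± 0.12) and Dcn (-0.57 ± 0.12; 5 adjusted over the list alone), of 7 resident macrophage genes Mrc1 (-0.996 ± 0.17; 3 adjusted over the list alone) and of 12 matrix genes Tnc (-0.66 ± 0.18; 2 adjusted over the list alone), which was at 0.61 with 16-µm bins and at 0.56 with all kept tissue. Ctla4 (-0.25 ± 0.28), Gzmb (0.47 ± 0.49), Cxcl10 (0.30), Gja1 (0.15), Nppa (0.35) and Nppb (0.01) did not pass. In all, 13 of 39 lists held a called gene.

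The T cell receptor beta segments, examined after the data had been seen, differed in their makeup between the hearts. Trbv19 made up 40.004% of 14006 Trbv UMIs in the male heart (39.2 to 40.8%) and 8.24% of 14767 in the female heart (7.80 to 8.70%). Trbv16 made up 16.8% in the female heart (16.2 to 17.4%) and 1.84% in the male heart. It was not the largest female segment, which was Trbv12-2 at 17.2% (16.6 to 17.8%), against 8.57% in the male heart (8.12 to 9.05%). In male patches with at least 50 Trbv UMIs, of which there were 16, the Trbv19 share ran from 18.8% to 53.3%, and in 9 female patches the Trbv16 share ran from 4.84% to 27.1%. Segments of 1 family can share probe sequence, and a segment in bulk counts gives no clone.

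**Figure D5:**
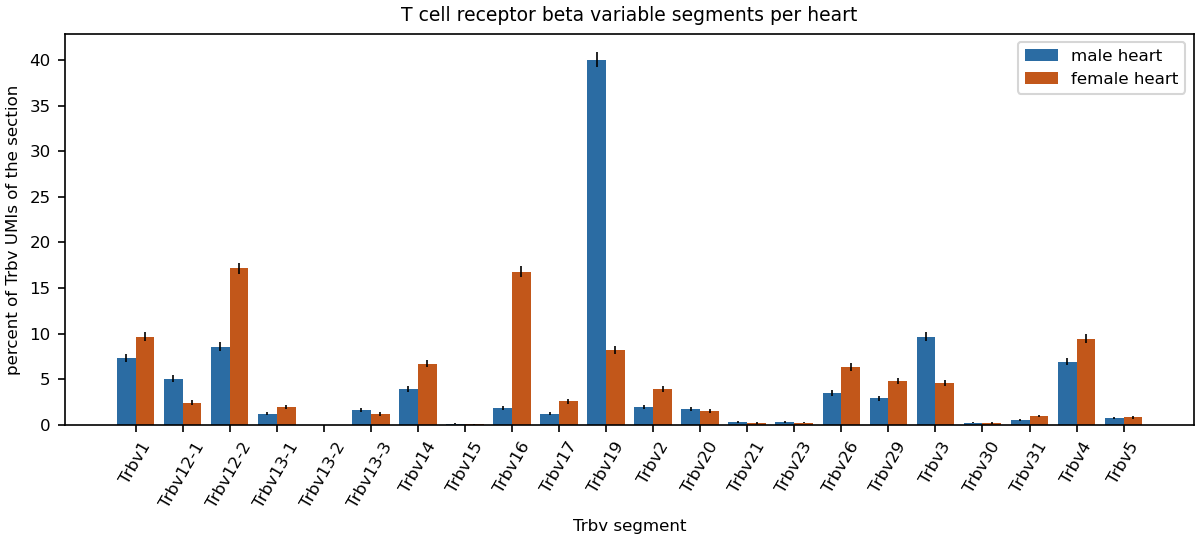
Share of each Trbv segment among all Trbv UMIs (y axis, %) in the male and the female heart, as bars with exact binomial 95% intervals. Trbv19 holds 40.004% in the male heart and Trbv16 holds 16.8% in the female heart, where Trbv12-2 holds 17.2%.

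Male and female sections were compared as values of 2 hearts, in which sex, animal and section plane go together. Of 11981 genes with at least 500 UMIs in a section, 540 differed at least 2-fold, 367 higher in the male and 173 in the female heart. Among the largest male ratios, male over female CPM was 10408 for Bpifa1 (95% interval 6995 to 16245), 9060 for Scgb1a1, 1986 for Sec14l3, 1588 for Scgb3a2, 1186 for Reg3g, 627 for Muc5b, 619 for Cyp2f2 and 507 for Myh8. Without extracardiac bins the ratio of Bpifa1 was 213 and that of Scgb1a1 was 169, and 210 genes were higher in the male and 209 in the female heart. Among the largest female ratios, female over male CPM was 49.1 for Arg1, an enzyme of alternatively activated macrophages, 45.0 for Cd5l, 42.0 for the scavenger receptor gene Marco, 39.1 for Saa3, 31.1 for S100a8, 28.5 for S100a9, 27.4 for the neutrophil receptor gene Cxcr2 and 22.4 for Fgf23, the phosphate-regulating hormone. These gaps were smaller in ventricular bins. Male over female CPM was there 0.389 for Arg1, 0.421 for Cd5l, 0.132 for Marco, 0.0763 for Saa3, 0.157 for S100a8, 0.169 for S100a9, 0.194 for Cxcr2 and 0.468 for Fgf23.

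Among lists, neutrophil genes had a median log2 male over female of -3.89, below all 10000 random lists (percentile 0), as did the monocyte-derived (-0.82), macrophage (-0.39), chemokine (-0.33), inflammasome (-0.44), matrix (-0.60) and blood (-1.27) lists. Atrial genes (2.95) and proliferation genes (1.06) lay at percentile 100, and adipocyte genes (1.71) at percentile 99.99. T cell genes lay at 0.08 (percentile 90.89) and cytotoxic genes at -0.21 (percentile 0.09). These ranks were taken over whole sections, which differ in anatomy, and were not repeated in ventricular bins. Of the monocyte-derived genes, male over female CPM turned there for Plac8 (2.09), Ccr2 (2.08) and Fcgr4 (1.36), and Spp1 was at 4.91. Arg1 (0.389), Chil3 (0.252) and Il1b (0.891) stayed higher in the female heart. The cytotoxic genes all lay above 1 in ventricular bins except Gzma (0.904), among them Ccl5 (1.22), Prf1 (1.20) and Nkg7 (1.46). All T cell genes lay above 1 there too, from Cd4 (1.03) to Tcf7 (2.84). Over whole sections, male over female CPM was 0.794 for Cd8a, 0.817 for Cd4, 0.572 for Ifng, 1.49 for Cxcl9, 1.38 for Nppa and 1.04 for Gja1. It was 0.891 for Ctla4, 1.24 for Gzmb, 0.848 for Cxcl10 and 0.771 for Nppb. In ventricular bins the direction turned for Cd8a (1.19), Cd4 (1.03), Ctla4 (1.62), Cxcl10 (1.40), Nppa (0.302) and Gja1 (0.914). Ifng was there at 1.001, Cxcl9 at 2.35, Gzmb at 1.89 and Nppb at 0.597.

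The extent of infiltration was compared at a shared leukocyte share of 0.806%. Of male bins 4.68% lay above it (4.53 to 4.83%) and of female bins 5.32% (5.15 to 5.49%), a difference of 0.638 percentage points. These intervals treat bins with overlapping windows as independent and are too narrow, so they do not show that the hearts differ. With T cell genes the difference was -2.18 points and in ventricular bins -3.49 points, so its direction depended on the measure. Leukocyte transcripts were also compared between atrial-class and ventricular-class bins. In the male heart they stood at 2107 CPM (2095 to 2120) in 33135 atrial-class and at 3456 CPM (3444 to 3469) in 41298 ventricular-class bins, a log2 ratio of -0.71. In the female heart they stood at 5698 CPM (5678 to 5719) in 22485 atrial-class and at 2347 CPM (2338 to 2356) in 45315 ventricular-class bins, a log2 ratio of 1.28. The female atrial class carried 3403 CPM of the atrial list and 18219 CPM of matrix genes, against 16643 and 4421 CPM in the male atrial class.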

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

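The test without extracardiac bins was chosen only after the result had been seen. Several lists moved in opposite directions in the 2 hearts, and these differences between hearts were not tested, since each sex has 1 heart. In foci against remote tissue the log2 ratio of the list's summed CPM, male then female, was -1.01 and 1.88 for Schwann and nerve genes, -5.27 and 3.04 for atrial genes, -3.24 and 0.43 for epicardial genes, -0.38 and 1.02 for fibroblast genes, and -1.51 and 1.46 for resident macrophage genes. In borders it was -0.72 and 2.54 for Schwann and nerve genes, -4.10 and 4.13 for atrial genes, -1.50 and 1.24 for epicardial genes, 0.17 and -0.23 for mural genes, and -1.12 and 1.45 for resident macrophage genes. As the median over genes the mural list was lower in both hearts, at -0.59 and -1.48. Remote tissue of the male heart was 56.5% atrial class and that of the female heart 7.67%. In ventricular bins only, foci were also set against tissue beyond 400 µm. On that measure all of these lists but the atrial list took the same direction in both hearts.

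UMIs were also counted outside the kept tissue, 4.65% of the male and 2.80% of the female total. Within 50 µm of tissue such bins held a mean of 218 and 236 UMIs, and beyond 400 µm 14.3 and 11.9, against 1801 and 2271 in kept bins.

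The leukocyte share of atrial-class over ventricular-class bins had a log2 ratio of -0.71 in the male and 1.28 in the female heart, a difference that was not tested. Bins of the male atrial class above the extracardiac cut were excluded as the whole cause, since without them the male ratio was 0.616 (0.611 to 0.620). The cut did not take out all such tissue. The bins above it held 71.8% of male Krt13 and 70.9% of male Krt4 UMIs. The 6743 female atrial-class bins with at least 0.3% atrial-list UMIs, 29.99% of the class, had a ratio of 2.40 (2.38 to 2.41). That cut is low beside the male atrial class, which carried 16643 CPM of the atrial list. Bins with little atrial muscle can pass it, so the test does not decide whether such bins explain the female ratio. The makeup of the female atrial class, sex, animal and section plane stay open.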

How the results depend on the processing

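Alternatives with atrial-class bins only, without extracardiac bins, without the density mask and with a mask at 1000 UMIs, and for distance ventricular bins, were chosen after seeing the data; the cause of a change was not tested unless stated. In foci, 1711 of 1892 alternative values of 112 named genes kept direction and side of the threshold, 126 no longer passed, 37 newly passed and 18 reversed. In borders the numbers were 1724 of 2001, with 233, 32 and 12. For CD8 bins 175 of 264 kept both and for neighbourhoods 134 of 275. With atrial-class bins 0 genes passed in either zone comparison, and log2 values turned in foci for Cd5l (-0.95), Spp1 (-0.19), Lox (-0.19), Fn1 (-0.40), Psmb10 (0.64), Ifit3 (0.56), Gbp6 (0.51), Igtp (0.74), Irgm1 (0.69) and the type I interferon list (0.71). In borders they turned for Spp1 (-0.52), Hcn4 (0.65) and Cd5l (-1.03). Camera's direction turned down for the proliferation list, whose median there was 0.0733. Library sizes only turned Cxcl12 (0.0738) and Ifit3 (0.0297) and gave 7006 border genes. Without the mask, Hbb-bt (0.0592), Hba-a2 (0.40) and the blood list (0.35) turned in foci and Hba-a2 (0.40) and the blood list (0.30) in borders. Zones from T cell genes turned S100a9 (-1.41), Cd5l (-0.17), Selp (-0.97) and the neutrophil list (-1.23) in foci and S100a8 (-0.73) in borders. Ventricular bins turned Dkk3 (1.66) and S100b (1.40) in foci, Ltf (0.61) and Dkk3 (1.68) in borders and the mural list against tissue beyond 400 µm (0.0891), and gave 7447 border genes. Matched remote bins turned Trdn (0.0891), Irx4 (0.98), Pdgfra (-0.52), Lum (-1.005) and Notch3 (-0.22) and gave 2387 border genes from 1380 male and 146 female bins drawn. Border and remote at 100 and 200 µm gave 2646 genes and the top 10% gave 2000 genes. With 16-µm bins the CD8 and CD4 bins gave 152 genes and the neighbourhoods 11, where Acta1 (-0.26) and Tnc (0.61) turned. With all kept tissue they gave 354 and 140 genes, and Plagl1 (0.0642), Ociad1 (-0.0398) and Tnc (0.56) turned. DESeq2 gave 12 and 16.

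Without the heart as a replicate block, 0 genes passed in the bins (408 unadjusted) and 0 in the neighbourhoods (469) by edgeR's quasi-likelihood test, while DESeq2 with the block gave 12 and 16; the zone comparisons gave 6043 and 4274. Of 26 lists called by camera in each zone comparison, 0 passed with an estimated correlation and 0 by fry, both of which have little power here. Other settings gave 22 to 31 in foci and 23 to 30 in borders. Leaving out a heart leaves no residual, so values have no test. Bmp10 ran from -0.31 in the male to 0.96 in the female heart for the bins, Ighm from -1.44 in the male to 0.0159 in the female heart for the neighbourhoods, and the count of cardiomyocyte-normalised lists higher in foci ran from 6 to 6. In atrial-class bins female ion channel genes moved from 1.90 to 0.47 and disc genes from 1.48 to 0.0547, and the mean of stress genes from 1.40 to 0.0974. Male against female gave 2094 genes in atrial-class bins. The female minus male share was 2.51 points at the 90th percentile, 0.173 at the 98th, 4.60 in atrial-class bins, -2.18 with T cell genes and -3.49 in ventricular bins. The atrial over ventricular log2 ratio was -0.88 and 1.39 at a 3-fold margin, -0.92 and 0.77 with T cell genes, and -0.70 in the male heart without extracardiac bins.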

Other observations

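The tests on CD8 bins and on Trbv segments were set down before their results were seen, for patterns first noticed in the data, and the test on CD3 transcripts was chosen after other Trbv results, in place of a focus enrichment that follows from how foci were set. Some neutrophil transcripts were higher in the female heart, with 20706 UMIs of S100a9 against 637 in the male heart, 13288 against 374 of S100a8 and 1189 against 38 of the receptor gene Cxcr2. Ly6g had 34 UMIs in the male and 39 in the female heart. In ventricular bins male over female CPM was 0.169 for S100a9 and 1.01 for Csf3r, against 0.398 for Csf3r overall. The proliferation list lay higher in the male heart at a median log2 of 1.06. Fgf23, a phosphate-regulating hormone gene, had 3324 UMIs in the female and 130 in the male heart, with male over female CPM at 0.468 in ventricular bins.

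CD8 bins carried more contractile transcripts than CD4 bins, at 3653 against 2633 CPM in the male and 5239 against 3339 CPM in the female heart, a log2 ratio of 0.47 and 0.65. Weighting CD8 bins to the CD4 bins by patch left a mean of 0.550, by UMIs per bin 0.562 and by distance to the edge of the focus 0.554, so that none of these explains it as a whole. No biological explanation of it was tested.

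Trbv19 was prominent among segments in the male heart and Trbv16 in the female heart. Trbv16 was not the largest female segment. Macrophages, monocyte-derived cells, dendritic cells, neutrophils and B cells, each taken by the sum of its list, were excluded as the whole source of either segment. A contribution from them, or from a subset that lies beside T cells, was not excluded. In foci the log2 CPM ratio of the segment between bins with and without a CD3 UMI was 0.75 in the male heart (0.58 to 0.92) and 0.74 in the female heart (0.40 to 1.07). The highest of these 5 lists was at -0.04 and 0.11, and the smaller gap was 0.624. The T cell gene Trac was at 0.60 and 0.54. Focus bins without a CD3 UMI held 564 Trbv19 UMIs in the male heart, against 591 in bins with CD3. For Trbv16 in the female heart the counts were 145 and 160. NK cells were not tested. A variant of the whole T cell pool, such as a sequence change under a probe, stays open. In all kept tissue the share in CD8 bins over that in CD4 bins was 1.496 in the male heart (1.20 to 1.88) and 1.52 in the female heart (1.09 to 2.17), while the bound set beforehand was a ratio above 1.5 in both hearts, which the male value missed. CD4 bins held only 283 and 327 Trbv UMIs. No biological explanation was tested, since the design names only sex.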
